A study of Picosynechococcus sp. PCC 7002 with 8 samples.

How the data were processed

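The series holds 8 total-RNA libraries of the unicellular marine cyanobacterium Picosynechococcus sp. PCC 7002 (formerly Synechococcus), grown in a turbidostat, a culture vessel that is diluted to hold cell density constant. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I, made into libraries with the SOLiD Total RNA-Seq kit and sequenced on a SOLiD 5500XL instrument. The labels divide the libraries into 5 conditions. Carbon, nitrogen and light limitation have 2 libraries each, and a strain adapted to high light and high oxygen has 1 library at 16.5% and 1 at 7.1% dissolved oxygen. The labels call these oxygen levels high and normal. No limited culture has a counterpart labelled as an unlimited control, and the labels state no limitation for the adapted strain.

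The authors deposited 1 table with an expression score for 3236 locus tags in 5 columns, 1 per condition, so that the 2 libraries of each limitation are combined into 1 value. How they were combined is not given in the sources used here, nor are the aligner, the counting method, the genome build, the annotation or the definition of the score. The deposited scores are whole numbers. Their quartiles nearly coincide between columns (medians of 40 to 43), while their sums run from 50806007 to 169587136. The scores were therefore treated as values already scaled between conditions, not as read counts, and no count model was applied. The depth behind the scores is unknown, because a rounded, scaled value does not show what 1 read is worth. No count-based interval or detection limit could be given. Rounding alone leaves each score uncertain by 0.5, which matters most for the 11.1% to 14.6% of locus tags per column with a score under 10.

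The tests planned before the data were examined (a model fitted to single libraries, and set tests on gene lists) needed values per library and gene symbols. The table used here gives neither, so they were not run and no p-value is given. With 1 column per condition, no difference has a replicate check. The identifiers were looked up in a RefSeq gene table of assembly GCF_963860125.1 with 3279 genes, of which 724 have a symbol of their own. That table lists other locus tags and no older ones, and 0 of the 3236 identifiers matched. The 23 gene lists fixed before the data were examined (among them phycobilisome, photosystems, carboxysome, inorganic carbon uptake, nitrogen assimilation, ribosomal proteins and oxidative stress defence) therefore had 0 members measured, and identifiers are given without names.

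Computed from the deposited scores, with Python 3.11, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, were log2 ratios of score + 1 between conditions. A pseudocount of 1 understates the change of low scores. A locus tag was kept if its score was at least 1 in 2 or more of the columns in the comparison. For limitations these were the 3 limitation columns, and for oxygen both adapted columns. The adapted strain was compared with the limited cultures as the mean log2 value of its 2 columns against that of the other 3. Locus tags that differed at least 2-fold were counted. The spread of a comparison is given as the median absolute deviation of its log2 ratios, scaled to match a standard deviation.

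The grouping by identifier and the class of very high scores were chosen after the table was seen, as was the level restriction except for oxygen, where it was planned. Each identifier has a letter from A to G and a number. For each letter with at least 4 members kept, the median log2 ratio was set against 10000 random lists of letter A locus tags of the same size, matched on mean level in 10 bins. This gives a percentile that describes these columns and is not a p-value. Because neighbours can move together, the medians were also set against all windows of as many consecutive letter A locus tags, after the median of letter A in each level bin was removed, a check added after the results were seen. These windows overlap. The share of other locus tags with like scores, given beside the specific sets in the adapted strain, was added at the same stage; these scores were matched in 10 bins of the limitation's own column. Runs were defined as 3 or more consecutive numbers of 1 letter that all differed at least 2-fold in 1 direction, and were set against 100 shuffles of the locus tags within each letter. Locus tags at least 2-fold above, or below, both other limitations were called specific to a limitation. The specific sets were set against the overlap of independent lists, and against 100 simulations of 3 unchanged columns. The simulated noise was normal and unrounded. Its size was set by the scaled median absolute deviation between carbon and light limitation in 10 level bins, with real differences between them counted as noise. Tails beyond a normal curve were left out.

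The locus tags named in each comparison are the 2 largest log2 ratios in each direction among those at or above the median, 5.40, of the mean of log2(score + 1) over the 5 columns. The rule fixed before the data were examined ranked genes by test and symbol and could not be applied as written. The files used here do not pair the identifiers with gene names, so the naming was limited to these. The counting was checked on simulated columns with 200 locus tags changed 4-fold and noise of 0.2 (log2). It recovered 200 for carbon against nitrogen and for carbon against light limitation, 199 for nitrogen against light limitation and for oxygen, and 200 for the adapted strain, with 0 unplanted calls in each. At this fold and noise that outcome follows from the 2-fold threshold, so it checks the computation and gives no rate of false calls for the deposited columns, whose spread is larger. All 20 planted runs were found, and 16 of 400 unchanged lists fell outside the middle 95% of their random lists. These lists were random picks with independent simulated values. They give no rate of false calls for the letters, whose neighbours can move together. The random lists are drawn with replacement, a choice made after a self-test showed that draws without it gave too narrow a range. Alternatives were median scaling, quantile normalization, other filters and pseudocounts, a 3-fold threshold, restriction to the higher-level locus tags, removal of very high scores, and windows of neighbours.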

Results

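The data describe the transcriptome of Picosynechococcus sp. PCC 7002, a cyanobacterium that lives on light, inorganic carbon and a nitrogen source such as ammonium. Carbon-limited cultures received 7.7 mM sodium bicarbonate. Nitrogen-limited cultures received 0.9 mM ammonium chloride, against 17 mM ammonium in the routine medium. Light-limited cultures grew under 140 microeinsteins per square metre per second. A strain adapted to high light and high oxygen was sampled at 16.5% and at 7.1% dissolved oxygen. The submitters used these conditions, with others, to build a gene co-expression network that groups genes by shared behaviour and links regulators to possible targets. The scores of each limitation are the authors' combined value of 2 libraries and those of the adapted strain come from 1 library each, so all differences below lack a replicate error.

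Most of the summed score lay in a small class of locus tags. The 47 locus tags with a mean score above 50000 held 98.4% of the sum under carbon limitation, 98.5% under nitrogen limitation, 98.2% under light limitation, and 99.5% in each adapted column. All 47 carried the letter A. The lowest mean in this class was 50895, the highest mean below it was 25777, and the median of the other means was 45.2. Outside this class the sums were similar: 983743 under carbon, 785324 under nitrogen and 990770 under light limitation, 857405 at high oxygen and 842284 at normal oxygen. Between 9 and 73 locus tags per column were listed at 0. Across locus tags, which are not independent replicates, carbon and light limitation had a Spearman correlation of 0.971. The adapted columns correlated at 0.968 with each other. Nitrogen limitation stood further off, at 0.858 from carbon and 0.885 from light limitation. The adapted columns lay between 0.748 and 0.824 from the limitation columns, nearest to light limitation.

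The comparison of carbon with nitrogen limitation asked how the transcriptome differed when 1 or the other nutrient set growth. Of 3228 locus tags, 288 were at least 2-fold higher and 366 at least 2-fold lower under carbon limitation, together 20.3%. Differences of at least 8-fold numbered 38 higher and 49 lower. Among locus tags at or above the median of mean log2 level, to which the named ones are limited, the neighbouring pair SYNPCC7002_A1292 and SYNPCC7002_A1291 differed most toward carbon limitation, at 992 against 9 and at 502 against 6, which are 99.3-fold and 71.9-fold on the score + 1 scale. Both were intermediate under light limitation, at 244 and 126. SYNPCC7002_A1827 (32 against 1403) and SYNPCC7002_A2395 (81 against 3443) were lower under carbon than under nitrogen limitation, 42.5-fold and 42.0-fold, and stood at 41 and 59 under light limitation.

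Locus tags with consecutive numbers often differed in the same direction in this comparison. Of those higher under carbon limitation, 112 lay in 22 runs of consecutive identifiers, against at most 22 locus tags in runs in 100 shuffles. Of those lower, 85 lay in 20 runs, against at most 31. The longest run of higher locus tags held 12 members of letter A, with median scores of 241.5 under carbon, 63 under nitrogen and 291 under light limitation. The longest run of lower ones held 9 members of letter D, with medians of 10, 239 and 12. By letter, 12 of 30 D locus tags, among them the 9 of this run, were at least 2-fold lower under carbon than under nitrogen limitation. None of the D locus tags was higher. G locus tags went the other way, with 39 of 163 higher and 16 lower. Their median log2 ratio of 0.28 lay above all 10000 matched lists, as did the median of 0.52 of the 39 E locus tags. Of these 39, 7 were at least 2-fold higher and 6 lower. Over the alternatives the G median ranged from 0.12 with a pseudocount of 10 to 0.86 at or above the median level, and the E median from 0.40 to 0.73. The median of the 30 D locus tags was -0.45, at percentile 5.66. Among locus tags at or above the median level the split turned, with 178 higher and 136 lower.

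**Figure D1:**
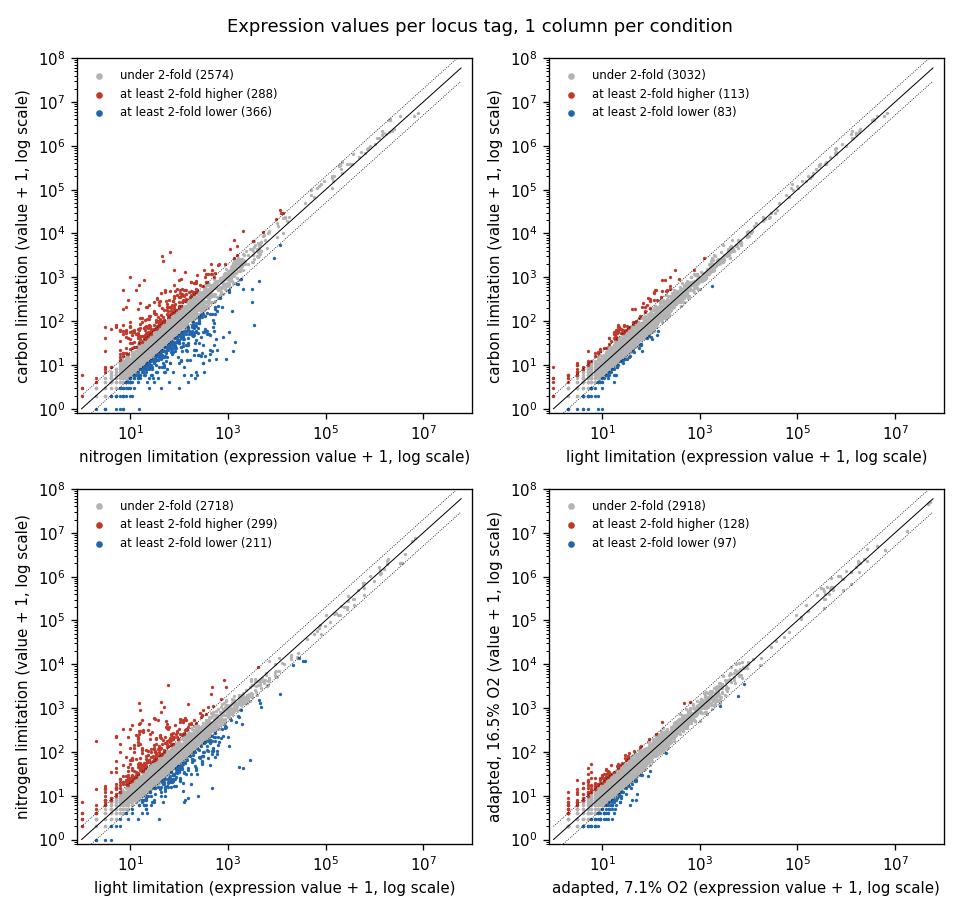
Expression score + 1 of each locus tag (points, log axes) in 4 pairs of conditions, with a solid line at equality and dotted lines at 2-fold. Points at least 2-fold apart are coloured: 654 for carbon against nitrogen limitation, 196 for carbon against light, 510 for nitrogen against light, and 225 for the 2 oxygen levels.

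Among the 3 pairs of limitations, carbon and light limitation differed least. Of 3228 locus tags, 113 were at least 2-fold higher and 83 lower under carbon limitation, together 6.07%, and 155 of these 196 had a mean level below the median. With quantile normalization the split was 113 higher and 44 lower, at the first-quartile filter 66 and 20, and with a pseudocount of 10 it was 53 and 8. SYNPCC7002_A2492 was 5.01-fold higher under carbon limitation (856 against 170), and SYNPCC7002_A0470 was 4.71-fold higher (1468 against 311). Both were lower still under nitrogen limitation, at 18 and 79. SYNPCC7002_A0034 was 3.10-fold lower (20 against 64) and SYNPCC7002_A2295 was 2.79-fold lower (634 against 1773). Runs held 35 of the 113 higher locus tags, against at most 6 in the shuffles, and 0 of the 83 lower ones. The longest run had 10 members of letter A with median scores of 70 under carbon, 23.5 under light and 10.5 under nitrogen limitation. Of the 163 G locus tags, 22 were higher and 9 lower, and their median log2 ratio of 0.11 lay above all matched lists, with 0.08 to 0.36 over the alternatives. The scaled median absolute deviation of the log2 ratios was 0.40, against 0.69 for carbon and nitrogen limitation.

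Nitrogen and light limitation differed at least 2-fold in 510 of 3228 locus tags, 299 higher and 211 lower under nitrogen limitation. Differences of at least 8-fold were 45 higher and 12 lower. SYNPCC7002_A2395 and SYNPCC7002_A1827 were again named, at 57.4-fold (3443 against 59) and 33.4-fold (1403 against 41) above light limitation. SYNPCC7002_A0140 was at the other end with 43 against 2043, 46.5-fold lower, followed by SYNPCC7002_A0582 with 64 against 2770, 42.6-fold lower. Runs held 70 of the higher locus tags, against at most 19 in the shuffles, and 91 of the lower ones, against at most 18. The longest run held 16 members of letter A with median scores of 63 under nitrogen, 238.5 under light and 218.5 under carbon limitation. The same run had medians of 394.5 and 357.5 in the adapted columns. Of the 163 G locus tags, 29 were lower and 11 higher under nitrogen limitation, with a median log2 ratio of -0.15, below all matched lists. Over the alternatives it ranged from -0.48 at or above the median level to -0.09 with a pseudocount of 10. Of the 39 E locus tags, 6 were higher and 5 lower. Their median was -0.31, at percentile 0.43, and ranged from -0.73 to -0.29. Among all locus tags at or above the median level, 107 were higher and 138 lower.

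Each limitation was then set against both others. Nitrogen limitation had the most specific locus tags, with 231 at least 2-fold above and 180 at least 2-fold below both carbon and light limitation. Carbon limitation had 69 above and 50 below, and light limitation had 10 above and 28 below. These 568 entries are 504 locus tags, since 64 were in 2 sets. Since the 2 comparisons behind each set share a column, some overlap arises without any effect: the simulations of unchanged columns gave at most 20 locus tags in any set. The simulated noise was unrounded and had no tails beyond a normal curve, so 20 is not an upper limit. The 10 locus tags specific to light limitation in the upward direction lay within the simulated range. The sets below both others under carbon and light limitation had a median score of 2 in their own column. The 50 became 23 with quantile normalization and 1 with a pseudocount of 10. The 28 became 1 with a pseudocount of 10 and 18 with median scaling, under the 20 that the simulations reached in any set and above the 15 they reached in this one. Independent lists of the observed sizes would have shared 33.9 and 18.8 locus tags for nitrogen, 10.1 and 9.41 for carbon, and 5.43 and 10.5 for light limitation, above and below. Of the 69 locus tags highest under carbon limitation, 43 were also at least 2-fold lower under nitrogen than under both other limitations. This set had median scores of 78 under carbon, 31 under light and 12 under nitrogen limitation, and 17 of its members were G locus tags. The 231 highest under nitrogen limitation had a median of 106, against 20 under carbon and 18 under light limitation. The 180 lowest under nitrogen limitation had a median of 34, against 198 and 120.

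The adapted strain, whose scores did not enter the choice of these sets, was then compared with the limitation that set each of them apart. Because each set was chosen for an extreme score in that column, part of any difference from it arises by selection, and the share of other locus tags with like scores in that column is given beside each count. Of the 69 locus tags highest under carbon limitation, 61 (88.4%) were at least 2-fold lower in both adapted columns, against 22.1% of the others, and the medians were 16 at high and 14 at normal oxygen. Of the 231 highest under nitrogen limitation, 167 (72.3%) were at least 2-fold lower, against 17.4%, with medians of 23 and 21. Of the 180 lowest under nitrogen limitation, 70 (38.9%) were at least 2-fold higher, against 13.5%, with medians of 76 and 73. The share was 23 of 50 (46.0%, against 23.1%) for those lowest under carbon limitation, 4 of 10 (40%, against 15.8%) for those highest under light limitation, and 12 of 28 (42.9%, against 17.1%) for those lowest under light limitation. Matching on 1 column does not remove the selection, since the sets also had to differ from 2 other columns. Letter was not matched either, and 17 of the 69 highest under carbon limitation were G and 3 were F locus tags. At least 2-fold lower in the adapted strain than in the limited cultures were 41.7% of G, 46.8% of F and 19.6% of A. Higher by as much were 6.13%, 5.50% and 17.1%.

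**Figure D2:**
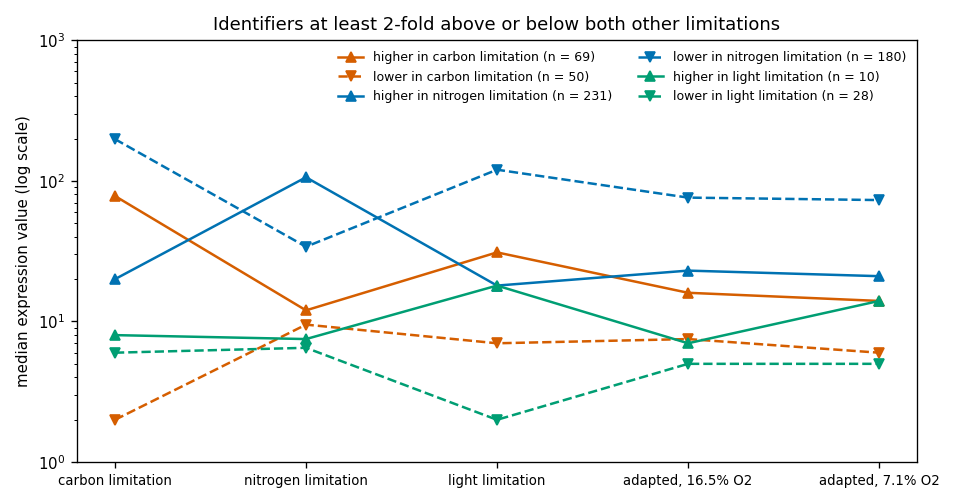
Median expression score (log axis) in each of the 5 columns for the 6 sets of locus tags at least 2-fold above (upward triangles, solid lines) or below (downward triangles, dashed lines) both other limitations. Lines join the points of 1 set. The set highest under nitrogen limitation had a median of 106 there and between 18 and 23 in the other 4 columns.

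High and normal oxygen were compared in the adapted strain, with 1 library each. Of 3143 locus tags with a score of at least 1 in both, 128 were at least 2-fold higher and 97 lower at 16.5% oxygen, together 7.16%. Of these 225, 197 had a mean level below the median, where rounding and low scores weigh most. Differences of at least 8-fold numbered 2. With locus tags at 0 in 1 of the 2 columns kept as well, 172 were at least 2-fold higher and 117 lower. SYNPCC7002_C0013 was 3.42-fold higher at high oxygen (40 against 11), and SYNPCC7002_A0410 was 3.27-fold higher (48 against 14). SYNPCC7002_A1962 was 3.17-fold lower (1867 against 5912), and SYNPCC7002_A1933 was 3.04-fold lower (27 against 84). Both higher ones drop out under a filter at the first quartile of scores. That filter asks for the quartile score in both adapted columns, so it removes them for their low score at normal oxygen. SYNPCC7002_A1962 was higher under carbon (20943), light (21340) and nitrogen (9486) limitation. Runs held 6 of the higher locus tags, equal to the highest of the shuffles, whose median was 0. They held 3 of the lower ones, against a median of 0 and at most 6 in the shuffles. The median log2 ratios of letters C to G lay between percentiles 9.15 and 90.0 of their matched lists. Of 27 D locus tags, 7 were lower and 1 was higher, 25.9% and 3.70%, against 2.51% and 3.51% of A locus tags. The run of lower locus tags was of letter D, with median scores of 5 at high and 12 at normal oxygen. The D median of -0.15 became 0.05 with the first-quartile filter. The scaled median absolute deviation was 0.42, beside 0.40 between carbon and light limitation. These spreads are not like measures: the oxygen columns are 1 library each, each limitation column combines 2, and the locus tags kept differ.

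The adapted strain differed from the limited cultures in strain and treatment together, and the labels give dissolved oxygen for the adapted cultures alone. Of 3229 locus tags, 529 were at least 2-fold higher and 697 lower in the mean of the adapted columns, together 38.0%. SYNPCC7002_A2215 was 27.4-fold higher, with 9599 and 16776 in the adapted columns and at most 527 in the others. SYNPCC7002_A1989 was 19.9-fold higher, with 764 and 644 against 23 to 56. SYNPCC7002_A2347 was 26.5-fold lower, with 69 and 44 against 885 to 2036, and SYNPCC7002_A1161 was 20.3-fold lower, with 10 and 12 against 127 to 532. Runs held 271 of the lower locus tags, against at most 156 in the shuffles, and 134 of the higher ones, against at most 73. The longest run of lower locus tags held 15 members of letter F, with medians of 3 and 2 in the adapted columns and 16 to 23 in the others. Of the 109 F locus tags, 51 were lower and 6 higher, with a median log2 ratio of -0.86. Of the 163 G locus tags, 68 were lower and 10 higher, with a median of -0.76. Both medians lay below all 10000 matched lists, and, with the level trend removed, below all windows of as many consecutive letter A locus tags. Quantile normalization and a pseudocount of 10 brought the G median to -0.38 and -0.34 and the F median to -0.58 and -0.52. The D median of -0.67 lay at percentile 1.2 and came to -0.33 and -0.31 under them. The E median of 0.43 lay at percentile 98.3 and ranged from 0.29 to 0.97. Of the 17 C locus tags, 7 were higher and 2 lower. Their median of 0.60 lay at percentile 97.2, inside the middle 95%, and ranged from 0.18 to 1.14. Over all 5 comparisons, 12 of the 25 medians of letters C to G lay outside the middle 95% of their matched lists. Neighbours moved together, so random lists are too narrow a reference, and the 3 limitation comparisons share columns. Against windows of consecutive letter A locus tags, 8 of the 25 lay outside the middle 95%. The G medians of the 3 limitation comparisons stayed beyond all windows, while 4 medians outside their matched lists lay inside that range: E between carbon and light limitation, E between nitrogen and light limitation, and D and E in the adapted strain (percentiles 96.6, 7.6, 4.51 and 95.7). With quantile normalization the split of the adapted comparison was 599 higher and 596 lower.

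**Figure D3:**
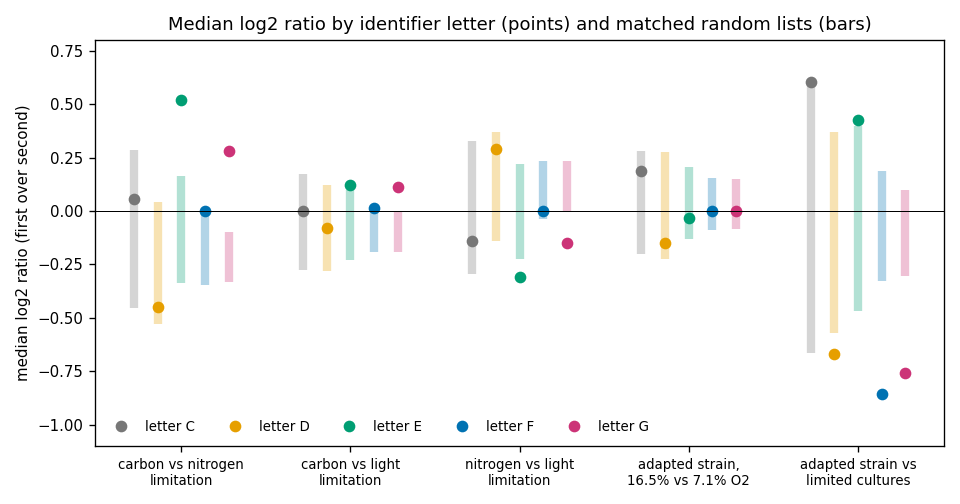
Median log2 ratio of the locus tags of letters C to G (points) in 5 comparisons, with bars over the middle 95% of 10000 level-matched random lists of letter A locus tags. The F and G medians in the adapted strain, at -0.86 and -0.76, lie below their bars.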

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

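The 3-fold threshold, the restriction to higher levels, the removal of the very high locus tags, every alternative of the adapted-strain comparison and the filter over all columns for oxygen were added after the data were seen, except that the first 2 were planned for oxygen. Of 62 recomputed counts for the comparisons and for the total of 568 over the specific sets (each locus tag counted once per set), 43 were within 1.5 times the count reported, including all under median scaling, quantile normalization and removal of the very high locus tags. Of 60 recomputed counts of single specific sets, 20 were lower than that, among them those lowest under light limitation with median scaling (18) and those lowest under carbon limitation with quantile normalization (23). The first-quartile filter and a pseudocount of 10 gave 5 and 1 in place of 50 lowest under carbon limitation, and 4 and 1 in place of 28 lowest under light limitation. A pseudocount of 0.1 changed no count except that of the adapted strain (1289), since whole scores then pass the same 2-fold line by construction. A pseudocount of 10 lowered the counts to 431 for carbon against nitrogen, 61 for carbon against light and 351 for nitrogen against light limitation. It gave 42 for oxygen, 834 for the adapted strain and 354 for the specific sets. The first-quartile filter lowered the counts to 458 for carbon against nitrogen, 86 for carbon against light and 351 for nitrogen against light limitation. It gave 31 for oxygen, 1030 for the adapted strain and 368 for the specific sets. At 3-fold they were 310 for carbon against nitrogen, 49 for carbon against light, 245 for nitrogen against light, 60 for oxygen, 620 for the adapted strain and 241 for the specific sets. At or above the median level they were 314, 41, 245, 28, 610 and 240, with 1618 locus tags tested in each comparison; the counts for carbon against light limitation and for oxygen fell further than that, as most of these differences lay at low levels. The median log2 ratio of F locus tags between carbon and light limitation, 0.02, became -0.017 with median scaling, which by construction shifts every ratio of a comparison by the same amount and here carried a value near 0 across it. Of the other letter medians reported outside their matched lists, none changed sign, but several moved by over 1.5 times, and F between carbon and nitrogen limitation, 0, ranged up to 0.26. No named locus tag changed sign where it was kept. Of the recomputed log2 ratios of named locus tags, 62 moved beyond the range left by rounding and 124 stayed within it. With a pseudocount of 10, SYNPCC7002_A1292 went from 6.63 to 5.72 between carbon and nitrogen limitation, and SYNPCC7002_A1161 from -4.34 to -3.59 in the adapted strain. Both named as higher at high oxygen are removed by the first-quartile filter. For oxygen that filter asks for the quartile score in both columns, so it removes locus tags for a low score in 1 of them. Part of the fall to 31 is thus built in. The main filter for oxygen also leaves out locus tags at 0 in 1 column, and with these kept the count was 289. No replicate could be left out and no other test tool or set test could be run, because the table gives 1 value per condition and no gene names. No paired analysis was possible because the labels give no shared replicate numbers and the columns are per condition. The unknown depth limits the low scores most: 79.1% of the counted differences between carbon and light limitation and 87.6% of those between oxygen levels lay below the median level.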

Other observations

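The tests of read sharing and of structural RNA genes in the class of very high scores were chosen after the values were seen; the other tests were set out before their results, but after the patterns they bear on had been seen. The locus tags set apart by a limitation were also followed in the oxygen comparison, whose columns did not enter their choice. Of the 231 highest under nitrogen limitation, 215 were measured at both oxygen levels, with 11 at least 2-fold higher and 13 lower at high oxygen and a median log2 ratio of 0 (percentile 28.7 of matched lists). Of the 180 lowest under nitrogen limitation, 173 were measured, with 4 higher and 7 lower and a median of 0.01 (percentile 22.1). The 7 measured locus tags highest under light limitation had a median of -0.40 at percentile 2.47, 1 of 6 sets looked at, with scores too low and too few to follow further. The 36 lowest under carbon limitation had a median of 0.10 at percentile 81.5, and the 20 lowest under light limitation one of 0.20 at percentile 86.8.

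A hypothesis was that carbon limitation and high oxygen share a response, because oxygen competes with carbon dioxide at Rubisco. The 63 measured locus tags highest under carbon limitation had a median log2 ratio of high to normal oxygen of 0.03, at percentile 59.5 of level-matched lists, with 4 at least 2-fold higher and 2 lower. The prediction of a shift was not met in these 2 libraries. The set is a weak probe, with median scores of 16 and 14 in the adapted columns against 78 under carbon limitation. Of its 69 members, 43 were also at least 2-fold lower under nitrogen than under both other limitations. The strain was, besides, adapted to high oxygen.

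The adapted and limited columns lie apart, with a scaled median absolute deviation of 1.13 for their log2 ratio against 0.69 between carbon and nitrogen limitation. A level-dependent distortion between the column sets would vanish once the running median over level is removed, but 1.10 remained, against 0.65 for carbon and nitrogen limitation. Imprecise low values would shrink the spread among the locus tags of highest level, but it was 1.04 above the upper quartile of level, against 0.63. A difference between library or sequencing batches stays open, since the labels give no batch and each column set is 1 kind of culture. The strain and its treatment stay open too and were not separable here.

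The F and G identifiers were lower in the adapted strain, and with the low level of the F identifiers and of the G identifiers matched in the random lists, both medians still lay at percentile 0, below all 10000, and below all windows of neighbouring letter A identifiers. Those windows overlap, and few of them are separate at this size. Whether a few runs of neighbours carry the median was tested by leaving out runs of lower neighbours: the F median stayed at -0.56, beyond the bound of -0.3 set in advance, while the G median was -0.19 without them; since the members left out were chosen for being lower, that rise decides nothing, and the explanation stays open for G. The 7 letters hold 2873, 165, 109, 39, 30, 17 and 3 identifiers (A, G, F, E, D, C and B), and the 7 sequences of the reference assembly hold 2894, 171, 115, 42, 35, 17 and 5 genes. It is a hypothesis that the letters mark the chromosome and the plasmids, and that F and G plasmids may be present in fewer copies, or be less transcribed, in the adapted strain. No DNA measurement was used here to separate these, and a batch difference stays open.

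Among the 47 locus tags in a separate class of very high values, 4 pairs lay within 10 percent of each other in all 5 columns, against 0 among the next 47, and the numbers of these pairs mirror each other, as in 2 inverted copies of 1 unit; they differed by at most 4.29%. The fifth mirrored pair differed by 6.84% to 19.4%, outside that limit. The 4 pairs are consistent with reads shared between near-identical copies. A candidate explanation for the class is structural RNA genes: the reference table has 2 units of 5 neighbouring rRNA and tRNA genes in opposite order, and 55 structural RNA genes in all. The sum of the class was 160815092 and 168744852 in the adapted columns against 50020683 to 60669014 in the others. The 2 highest locus tags of each column held 60.7% and 58.8% of the column sum in the adapted columns, against 17.3% to 28.0% in the others. The difference in sums was therefore not spread evenly over the 47. How much rRNA was removed from each library is not given in the sources used here.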
